A study of Homo sapiens with 27 samples.

How the data were processed

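RNA of SH-SY5Y cells, a human neuroblastoma line, was measured on Affymetrix arrays with biotin-labelled RNA. The 27 arrays form 9 groups of 3, and the labels call the 3 arrays of a group biological replicates. The deposited table holds 1 log2 expression value per probe set and array. The authors made these log2 values with the R package oligo, per the submitters' processing notes, and its version, the background correction and the normalization method are not given in the sources used here. The log2 scale was taken from the values, which run from 0.699 to 12.8 on the 27 arrays. No further transformation was applied before the main analysis, and no scanner files were used here. The precision of an array study is limited by the number of arrays, here 3 per group.

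The table holds 53617 probe sets. The platform annotation used here lists 25713 of them, of which 23871 carry 1 gene symbol and 1842 carry several. The remaining 27904 are unnamed here. Symbols were updated through gene identifiers against the RefSeq gene table of assembly GRCh38.p14, in which 22569 probe sets were matched and 98 symbols changed. Probe sets with several symbols or none entered no gene comparison. For the 632 genes with more than 1 probe set, the probe set with the highest mean over all arrays was used. This left 22395 genes, and no filter on dim genes was applied.

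Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided). A single model with the 9 group means was fitted to all 27 arrays, so that the groups shared 1 estimate of the spread with 18 residual degrees of freedom and 6.4 prior degrees of freedom. The SE of a gene's log2 difference rests on this shared estimate, not on the spread of the compared groups alone. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, with no minimum fold. The comparisons were C2-ceramide against control, C2-ceramide with PJ34 against C2-ceramide and C2-ceramide with PJ34 against control at 3, 6 and 24 h, and control cells at 24 h against 3 h. The mean of the 3 within-time differences was tested in the same model, and an F test asked whether a difference changed between the 3 times.

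The 40 gene lists were fixed before the data were examined, as were the design, the alternatives listed first below and the rule for named genes. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were alternatives. Members were also counted after adjustment over the list alone. The named genes of each comparison of C2-ceramide with control, and of the inhibitor group with C2-ceramide, are the 8 with the largest positive and the 8 with the largest negative log2 difference. They had to be called, and the 3 arrays of each group had to lie apart from the 3 of the other, which happens for 10% of unchanged genes by chance. For the remaining comparisons 4 and 4 were taken. Unnamed transcripts and small RNA precursors were passed over. Up to 4 members of each described list, those with the smallest adjusted p, were added, and PARP1, SIRT1, SPHK1, SPHK2, BCL2, BAX, CDKN1A, CYP1A1 and TIPARP were named whatever their values. SPHK2 had no probe set with a single symbol and has no value. Genes outside this rule are said to be chosen after their values were seen.

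The model was tested on simulated data with the real genes' means and spreads. Genes were drawn independently and with the same spread on every array. The real arrays varied unequally, so the rates below need not hold for them. For C2-ceramide against control at 24 h, over 22395 genes, it recovered 36% of 50 genes changed by 0.5 on the log2 scale, 98% of those changed by 1 and 100% of those changed by 1.5 or 2, with 7 calls among unchanged genes. The alternatives were leaving out the 30% dimmest genes, quantile normalization again, a replicate block, eBayes with trend and robust, the mean of a gene's probe sets, array weights, a fit of only the groups compared, and leaving out each array in turn. An array's interquartile range as a covariate, and a fit without the least correlated arrays, were added after the data were seen. For comparisons that share a group, its 3 arrays were also divided between them, 1 and 2, in the same kind of model, likewise chosen after the data were seen. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.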

Results

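The experiment asked how SH-SY5Y cells, a human neuroblastoma line of neuroblast morphology, respond to a short-chain ceramide and to inhibition of PARP-1, the main enzyme that attaches poly(ADP-ribose) to proteins at DNA breaks. Cells kept in low-serum medium received 25 µM C2-ceramide, a cell-permeable analogue of the lipid messenger ceramide, or 25 µM C2-ceramide with 20 µM of the PARP inhibitor PJ34, or medium alone as the control. RNA was collected at 3, 6 and 24 h from 3 biological replicates of each of the 9 groups, and 22395 genes were compared on 27 arrays. The labels give the control as pure medium and name no vehicle, so an effect of a solvent, if one was used, cannot be separated from that of C2-ceramide in any difference from control. No group received PJ34 alone, so the inhibitor group against the C2-ceramide group can show effects of PJ34 only in the presence of ceramide. The arrays' median log2 values ran from 3.74 to 3.93. Replicate 3 of the inhibitor group at 3 h and replicate 3 of the C2-ceramide group at 24 h were the least correlated with the others, with a median r of 0.952 and 0.971. In every comparison below the median log2 difference of all genes lay between -0.026 and 0.010.

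**Figure D1:**
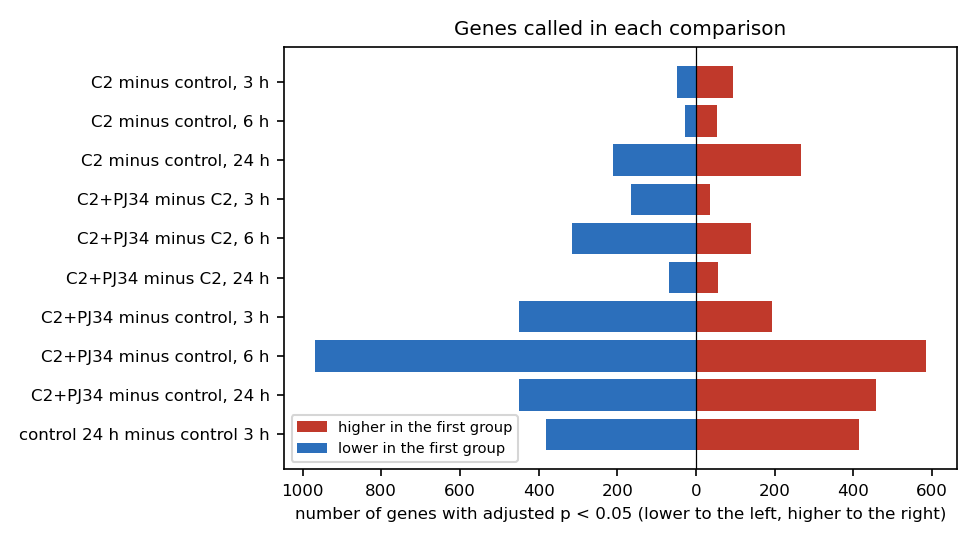
The bars show the number of genes with an adjusted p under 0.05 in each comparison, those lower in the first-named group to the left and those higher to the right of 0. The inhibitor group against control at 6 h had the most, 969 lower and 586 higher.

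At 3 h C2-ceramide raised CHAC1, an enzyme that degrades glutathione, by 1.42 (log2, SE 0.20, 3 arrays per group) and lowered TXNIP, an inhibitor of thioredoxin, by a log2 difference of -1.78 (SE 0.22). The related arrestin-domain gene ARRDC4 fell too (adjusted p = 0.00685), as did CCN1, a secreted matrix protein (-2.06), and CSRP1, an actin-associated LIM protein (-1.29). EPPK1 (-1.23), SLITRK6 (-1.23), ARID5B (-1.13) and EIF2AK3, which encodes the stress kinase PERK (-1.07), were the other largest decreases. LAMB4, a laminin chain, had the largest increase at 2.41 (SE 0.20, adjusted p = 2.37e-07). The bitter taste receptor gene TAS2R3 (1.30), the placental transcription factor gene GCM1 (1.28), SLC6A16 (1.28), MINAR2 (1.39), APRG1 (1.40) and the olfactory receptor pseudogene OR10AB1P (1.43) also rose. Together 93 genes were higher and 47 lower by limma.

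Among 40 measured targets of ATF4, the transcription factor of the integrated stress response, 3 rose at 3 h, CHAC1, DDIT4 (1.07) and VEGFA (0.52), and 11 rose adjusted over the list alone. DDIT3, which encodes CHOP, had a log2 difference of 1.13 with an adjusted p of 0.0568. The list stood above other genes by camera (adjusted p = 3.78e-11), with an adjusted p = 0.802 with an estimated correlation. Of 24 cholesterol genes 1 rose and 4 rose adjusted over the list alone (camera adjusted p = 8.54e-06, and adjusted p = 0.802 with an estimated correlation). ERN1, the gene of the unfolded-protein sensor IRE1, rose by 0.63. Leaving out C2 replicate 1 or 2 gave 86 or 82 genes, and leaving out control replicate 1 or 2 gave 79 each. A fit of only the 6 arrays compared gave 56 genes.

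At 6 h GDF15, a secreted cytokine induced by cell stress, rose by 3.26 (SE 0.38, adjusted p = 5.91e-05, 3 arrays per group), SLC7A11, the cystine importer, by 2.71 (SE 0.38) and EGR1, an immediate early transcription factor, by 2.30 (SE 0.25). CHAC1 (1.65), DDIT3 (1.62) and SESN2, a stress-induced inhibitor of mTORC1 signalling (1.33), rose with them, as did VGF, a neurosecretory protein (1.42), and LAMB4 (1.67). TXNIP (-1.56) and ARRDC4 (-0.87) were again lower, and so were the actin-associated genes CNN2 (-1.16), VCL, which encodes vinculin (-1.05), and CSRP1 (-0.88), together with RPH3A (-0.90), EPPK1 (-0.86) and SLC4A8 (-0.83). In all, 54 genes were higher and 29 lower.

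Of the 40 ATF4 targets 13 rose and none fell at 6 h, and 24 rose adjusted over the list alone (camera adjusted p = 5.95e-43, and adjusted p = 0.0148 with an estimated correlation). Among 36 immediate early genes, EGR1 and ZFP36 (1.05) rose, and 11 rose and 1 fell adjusted over the list alone (camera adjusted p = 7.49e-08, and adjusted p = 0.135 with an estimated correlation). Of 25 NRF2 targets and antioxidant genes SLC7A11 and SQSTM1 (0.62) rose, and 3 rose adjusted over the list alone (camera adjusted p = 0.000303, and adjusted p = 0.135 with an estimated correlation). SLC2A1, the glucose transporter GLUT1 (0.82), and VEGFA (0.80) were the 2 of 34 hypoxia and glycolysis genes that rose, while 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00185, and adjusted p = 0.513 with an estimated correlation). Leaving out C2 replicate 1, C2 replicate 2 or control replicate 3 gave 46, 55 and 55 genes. With the array interquartile range as a covariate the split was 116 higher and 143 lower.

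At 24 h C2-ceramide kept GDF15 (3.26, SE 0.38), SLC7A11 (2.26, SE 0.38) and EGR1 (2.33, SE 0.25) above control and raised VGF by 2.47 (SE 0.21, adjusted p = 2.6e-07, 3 arrays per group). The transcription factor genes JUN (1.82), KLF6 (1.79) and KLF2 (1.67) and the TWEAK receptor gene TNFRSF12A (1.73) were the other largest increases. For GDF15 and SLC7A11 the ceramide arrays at 24 h varied more than the control arrays. GDF15 was 7.69, 9.70 and 7.82 with ceramide and 5.35, 4.77 and 5.31 in control. SLC7A11 was 6.01, 7.17 and 5.08 with ceramide and 3.94, 3.62 and 3.92 in control. Each ceramide array lay above every control array, but the SE of 0.38, from the spread shared by all groups, may understate the uncertainty here. FLRT3, a neuronal adhesion protein, had the largest decrease (-1.57), followed by SUSD2 (-1.41), CNTNAP4 (-1.35), BCRP3 (-1.23), the histone genes H1-5 (-1.22) and H3C13 (-1.22), DPT (-1.19) and OCA2 (-1.17). In all, 268 genes were higher and 212 lower. In control cells EGR1, KLF6 and TNFRSF12A fell and BCRP3 rose between 3 and 24 h, as given below. A difference from control at 24 h thus need not be a change within the treated group.

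Of 36 immediate early genes 12 rose and 1 fell at 24 h, with KLF6, EGR1, ZFP36 (1.57) and RHOB (1.18) having the smallest adjusted p, and 17 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.28e-14, and adjusted p = 0.0275 with an estimated correlation). Many of these genes fell in control cells between 3 and 24 h, as given below. EGR1 itself was lower in the ceramide arrays at 6 h (8.94, 9.26 and 8.29) and 24 h (8.13, 8.82 and 8.35) than at 3 h (10.39, 9.91 and 9.99). NQO1, a quinone reductase (1.53), SQSTM1 (0.87), ABCC3 (1.00) and SLC7A11 were the 4 of 25 NRF2 targets that rose, and 8 rose adjusted over the list alone (camera adjusted p = 5.49e-07, and adjusted p = 0.0275 with an estimated correlation). Of the ATF4 targets 14 rose, among them SLC6A9 (1.05) and CEBPB (1.09), and 24 rose adjusted over the list alone (camera adjusted p = 7.6e-21, and adjusted p = 0.0982 with an estimated correlation). Of 58 mitosis genes 15 fell, with MKI67 (-0.58), KIF20A (-0.75) and NUSAP1 (-0.64) among them, and 50 fell adjusted over the list alone (camera adjusted p = 2.73e-32, and adjusted p = 0.0982 with an estimated correlation). Of 44 DNA replication genes 10 fell, including UHRF1 (-0.70), RRM2 (-0.64) and RFC3 (-0.72), and 23 fell adjusted over the list alone (camera adjusted p = 7.6e-21, and adjusted p = 0.0982 with an estimated correlation). Among 30 noradrenergic neuroblast markers SCG2 rose (0.90) and 4 fell, including DDC, the enzyme that makes dopamine (-0.79), CHGA (-0.95) and HAND1 (-0.66), while 1 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.000639, and adjusted p = 0.255 with an estimated correlation). In control cells SCG2 fell and CHGA and HAND1 rose between 3 and 24 h, as given below. These differences thus need not be changes within the ceramide group. The BH3-only gene BBC3 rose (0.67) and BID fell (-0.67) in the pro-apoptotic BCL2 family. In sphingolipid metabolism PLPP3, a lipid phosphate phosphatase, fell (-0.86), and in NAD metabolism CD38, an NAD-consuming enzyme, fell (-0.75).

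The 24 h count moved with single arrays. Leaving out C2 replicate 2 gave 117 genes, and leaving out control replicate 1, 2 or 3 gave 283, 218 and 174, while a fit of only the 6 arrays compared gave 20. With the array interquartile range as a covariate the split at 24 h was 595 higher and 760 lower.

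**Figure D2:**
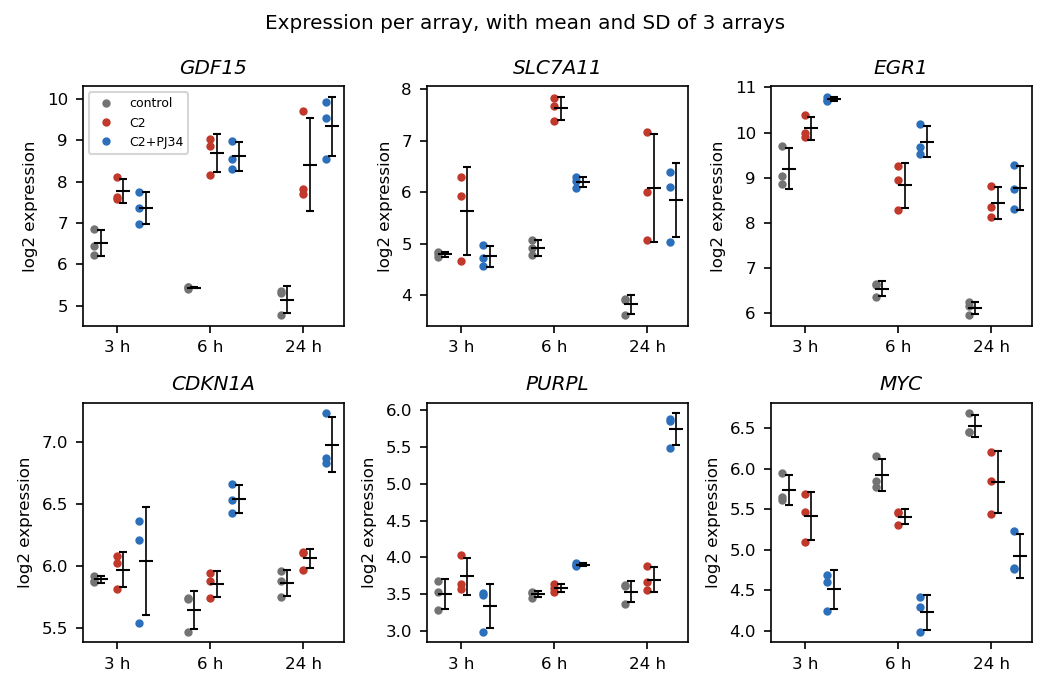
Each point is the log2 expression of a gene on 1 array, for control, C2-ceramide and C2-ceramide with PJ34 at 3, 6 and 24 h, and the black lines are the mean and SD of 3 arrays. GDF15 and EGR1 lie above control with ceramide at 6 and 24 h, SLC7A11 is lower with PJ34 than with ceramide alone at 6 h (-1.43), and PURPL is higher with PJ34 at 24 h (2.04).

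Averaged over the 3 times, 453 genes were higher and 472 lower with C2-ceramide than in control, and with the array interquartile range as a covariate 833 were higher and 1491 lower. The effect differed between the times for 45 genes. KLF6 had the smallest interaction p of the named genes (adjusted p = 0.00017), with log2 differences of -0.17, 0.45 and 1.79 at 3, 6 and 24 h. CCN1 ran from -2.06 at 3 h to 0.35 at 24 h (adjusted p = 0.00137). Both KLF6 and CCN1 also fell in control cells between 3 and 24 h, as given below. Their changing difference thus need not be a change in the ceramide group. LAMB4 ran the other way, from 2.41 to 0.22 (adjusted p = 0.00137). Leaving out C2 24 h replicate 2 or C2 3 h replicate 1 gave 25 or 29 such genes.

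With PJ34 added to ceramide, the 3 h arrays showed ANKUB1 (1.41, SE 0.22, 3 arrays per group) and ADAM20, a testis-type metalloprotease gene (1.18, SE 0.16), above ceramide alone, along with LINC00310 (1.06), ADAMTSL4-AS1 (0.88), SLC25A52 (0.88), HMGN2 (0.79), CTHRC1 (0.76) and LSMEM1 (0.73). LAMB4 (-1.37, SE 0.20) and OR10AB1P (-1.37), both raised by ceramide at this time, were lower. The other largest decreases were LHX4-AS1 (-1.32), PCDH18 (-1.32), FLRT3 (-1.30), KCNH1-IT1 (-1.27), GPR22 (-1.26) and SLC29A3 (-1.19). The growth regulator MYC fell (-0.90), as did the phosphatase gene DUSP4 (-0.74) and the BH3-only gene BCL2L11 (-0.59). VEGFA (-0.56) was the only 1 of 40 ATF4 targets that fell, also adjusted over the list alone (camera adjusted p = 0.000508, and adjusted p = 0.682 with an estimated correlation). Spliceosomal and other small nuclear RNAs were higher in 17 of 17 (median 0.23, camera adjusted p = 0.0274, and adjusted p = 0.804 with an estimated correlation), and snoRNA genes in 22 of 25 (median 0.26, camera adjusted p = 0.00828, and adjusted p = 0.677 with an estimated correlation). Without the 2 least correlated arrays, of which inhibitor replicate 3 belongs to this comparison, the medians were 0.04 for small nuclear RNAs, 0.18 for snoRNA genes and -0.10 for ATF4 targets, against -0.19 with all arrays (camera adjusted p = 0.895, 0.101 and 0.0369). Other lists newly passed without them. Mitosis genes went from a median of -0.02 (camera adjusted p = 0.632) to 0.16 (4.62e-05), and ribosome biogenesis genes from 0.01 (0.852) to 0.13 (0.0141). In all, 36 genes were higher and 166 lower, against 89 and 219 after quantile normalization, 127 and 272 with the array interquartile range as a covariate and 65 and 81 without the 2 least correlated arrays. Leaving out C2 replicate 1, C2 replicate 3 or inhibitor replicate 3 gave 81, 104 and 110 genes, and a fit of only the 6 arrays compared called 0 genes by limma, with 1241 at an unadjusted p under 0.05.

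At 6 h PJ34 raised C2orf66 by 1.51 (SE 0.11, adjusted p = 1.88e-08, 3 arrays per group), TAS2R9 by 2.08, ADAM20P1 by 2.02, ANKUB1 by 1.92 and ADAM20 by 1.63 over ceramide alone, followed by BCO2 (1.29), ADAMTSL4-AS1 (1.13) and PPIEL (1.11). SLC7A11 (-1.43, SE 0.38) and MYC (-1.18, SE 0.18) fell, as did GPR22 (-1.33), PRR16 (-1.28), the potassium channel gene KCNH1 (-1.22), the phosphodiesterase gene PDE7B (-1.16), CHML (-1.09) and NRG1-IT3 (-1.06). Of 28 p53 targets 5 rose, with DDB2 (0.55), CDKN1A, which encodes the cell-cycle inhibitor p21 (0.69), SESN1 (0.51) and TIGAR (0.59) having the smallest adjusted p, and 9 rose adjusted over the list alone (camera adjusted p = 3.19e-07, and adjusted p = 0.102 with an estimated correlation). Of the 40 ATF4 targets 6 fell, among them SLC7A5 (-1.05), CHAC1 (-0.89), DDIT4 (-0.74) and XPOT (-0.77), and 20 fell adjusted over the list alone (camera adjusted p = 1.72e-12, and adjusted p = 0.399 with an estimated correlation). Among 30 noradrenergic markers ELAVL4 (-0.69) and SLC18A1 (-0.54) fell, and 4 fell adjusted over the list alone (camera adjusted p = 0.000947, and adjusted p = 0.411 with an estimated correlation). In all, 139 genes were higher and 316 lower, against 478 and 506 with the array interquartile range as a covariate. Leaving out C2 replicate 1, 2 or 3 gave 196, 199 and 160 genes, and leaving out inhibitor replicate 1, 2 or 3 gave 228, 171 and 231. The 228 were 95 higher and 133 lower.

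At 24 h PURPL, a p53-regulated long noncoding RNA, was higher by 2.04 with PJ34 than with ceramide alone (SE 0.15, adjusted p = 8e-09, 3 arrays per group). EDA2R, a receptor gene of the tumour necrosis factor receptor family (1.05), the histone genes H3C13 (1.34) and H2BC18 (1.21), H2BC20P (1.14), ISL1-DT (0.93), SMIM32 (0.93) and DOK4 (0.92) also rose. RN5S63 (-1.67), RAB27B, a regulator of vesicle secretion (-1.62, SE 0.22), the protease gene ADAMTS1 (-1.20), TRIL (-0.95), TNS3 (-0.92), MYC (-0.91), CYTL1 (-0.88) and PLXNA4 (-0.86) fell. Of 28 p53 targets 6 rose, with DDB2 (0.76), EDA2R, TIGAR (0.86) and CDKN1A (0.91) having the smallest adjusted p, and 20 rose adjusted over the list alone. That list passed camera both ways (adjusted p = 4.26e-19, and adjusted p = 0.000714 with an estimated correlation). Small nuclear RNAs were lower in 17 of 17 (median log2 difference -0.42, camera adjusted p = 0.000353, and adjusted p = 0.952 with an estimated correlation), and snoRNA genes in 22 of 25 (median -0.28, camera adjusted p = 0.00112, and adjusted p = 0.952 with an estimated correlation). Without the 2 least correlated arrays, of which C2 replicate 3 belongs to this comparison, the medians were -0.01 for spliceosomal and other small nuclear RNAs and -0.06 for snoRNA genes (camera adjusted p = 0.677 and 0.586). ATF4 targets had a median of -0.07 with all arrays (camera adjusted p = 0.292) and of -0.21 without those 2 arrays (camera adjusted p = 1.42e-06). NQO1 was a further 0.75 above ceramide alone. In all, 55 genes were higher and 69 lower, against 76 and 56 without C2 replicate 1 and 65 and 111 after quantile normalization. Leaving out C2 replicate 2 or 3 gave 77 and 59 genes, leaving out inhibitor replicate 1, 2 or 3 gave 47, 35 and 35, and a fit of only the 6 arrays compared gave 1.

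The genes of the drug's target and of the lipid and death pathways were measured too. PARP1 had log2 differences of -0.25, -0.20 and -0.38 with C2-ceramide at 3, 6 and 24 h (SE 0.12, adjusted p = 0.657, 0.706 and 0.0956) and passed in none of the comparisons. SIRT1, SPHK1, BCL2, BAX, CYP1A1 and TIPARP also passed in none. CDKN1A passed with PJ34 against ceramide alone at 6 and 24 h, and its log2 difference with ceramide against control was 0.08, 0.21 and 0.20.

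Averaged over the times, PJ34 with ceramide gave 313 genes higher and 759 lower than ceramide alone, against 556 and 829 after quantile normalization and 1110 and 1133 with the array interquartile range as a covariate. The difference changed between the times for 32 genes, and PURPL (adjusted p = 8.95e-07) and C2orf66 (adjusted p = 3.75e-05) had the smallest interaction p of the named genes. PURPL differed by -0.41, 0.31 and 2.04 at 3, 6 and 24 h, and C2orf66 by 0.20, 1.51 and 0.13. ANKUB1 and ADAM20 were high at 3 and 6 h and near ceramide alone at 24 h (-0.20 and 0.04, adjusted p = 0.00396 and 0.0042). This count fell to 17 without C2 24 h replicate 3, 21 without C2 6 h replicate 2, 14 without C2 3 h replicate 1 and 10 without C2 6 h replicate 3, and to 12, 17 and 12 without inhibitor 24 h replicate 1, 2 and 3. It was 18 without inhibitor 3 h replicate 2, 13 and 10 without inhibitor 6 h replicate 1 and 2, 61 without C2 24 h replicate 1 and 60 without inhibitor 3 h replicate 1.

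**Figure D3:**
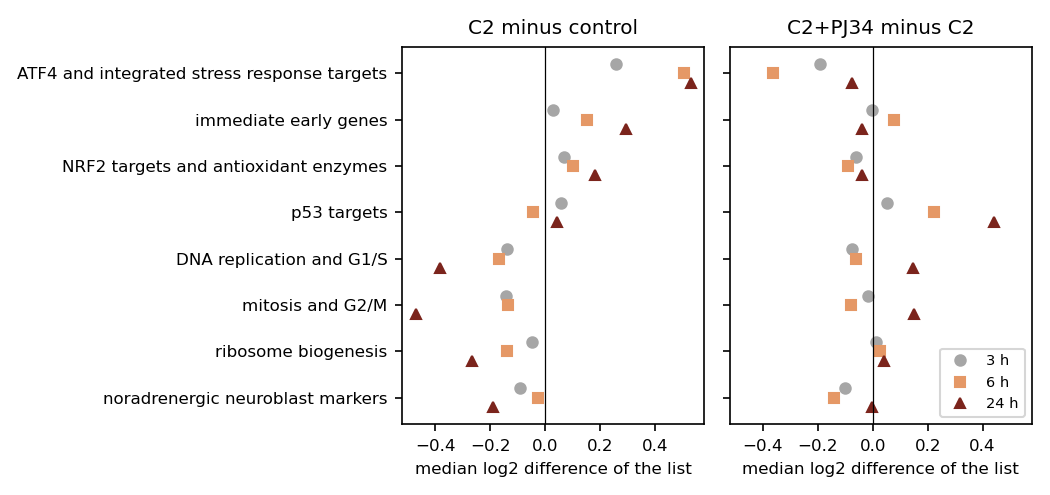
Points are the median log2 difference of the measured members of 8 gene lists at 3, 6 and 24 h, for C2-ceramide against control on the left and C2-ceramide with PJ34 against C2-ceramide on the right. ATF4 targets lie above 0 on the left at all 3 times, and p53 targets rise to 0.44 on the right at 24 h.

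Genes called both with ceramide against control and with PJ34 against ceramide alone share the ceramide arrays with opposite sign. At 3 h there were 35, of which 27 were higher with ceramide and lower with PJ34, LAMB4, GCM1, VEGFA and SLC29A3 among them. At 6 h there were 17. SLC7A11 (2.71 then -1.43), CHAC1, DDIT4 and SLC7A5 were raised by ceramide and lower with PJ34, while EGR1 was raised by ceramide and higher again with PJ34 (2.30 then 0.96). At 24 h there were 21, of which 9 were higher then lower and 7 lower then higher, and MYC (-0.70 then -0.91) and RAB27B (-1.10 then -1.62) fell in both steps. Independent lists of these sizes would share 0.69 genes in the higher then lower class at 3 h, 0.76 at 6 h and 0.83 at 24 h. In 20 simulations of unchanged groups at most 0 genes were shared, but at most 3 genes were called in any of these comparisons, so that 0 is no measure for lists of the sizes found. Across genes the correlation of the differences was -0.24, -0.13 and -0.42 at 3, 6 and 24 h, against -0.50 in the simulations, and the covariance was -0.0096, -0.0053 and -0.0211 against -0.0133, -0.0132 and -0.0132. The simulations gave all arrays the same spread, but the C2 24 h group holds 1 of the 2 least correlated arrays. The more negative covariance at 24 h thus cannot be told from the larger spread of that array. The 3 ceramide arrays were also divided, 1 for one comparison and the other 2 for the other, in 6 ways at each time, with the lone array assumed to vary like the other groups. Then 2 to 14, 0 to 2 and 1 to 43 genes were called in both at 3, 6 and 24 h, of which 2 to 11, 0 to 0 and 0 to 3 were higher then lower, and 0 to 5, 0 to 2 and 0 to 35 moved in the same direction in both. The mean covariance was 0.0040, 0.0046 and 0.0014, against 0.0001, -0.0002 and 0.0002 for 1 simulation of unchanged groups divided in the same way. At 24 h the 43 and the 35 came from 1 division. It set C2 replicate 3, 1 of the 2 least correlated arrays, alone against the inhibitor group. Its covariance was 0.0102, and the others at 24 h ran from -0.0127 to 0.0068. The positive mean at 24 h rests on that division. A negative mean covariance across genes was thus not seen once the arrays were divided, though single divisions at 3 and 24 h gave both signs. Fewer arrays also called fewer genes in most of these divisions, so the part of the overlap that comes from the shared arrays is not known.

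Ceramide with PJ34 was also compared with untreated control. At 3 h ANKUB1 (2.35), ADAM20P1 (2.28), ADAM20 (2.01) and ADAMTSL4-AS1 (1.88) rose most, and GPR22 (-2.09), CCN1 (-2.07), SLITRK6 (-2.07) and TXNIP (-2.01) fell most, among 193 higher and 449 lower genes, against 353 and 567 after quantile normalization, 329 and 437 with array weights, 286 and 341 without the 2 least correlated arrays and 208 and 254 without inhibitor replicate 3. A fit of only the 6 arrays compared gave 38 genes at 3 h, where the same kind of fit gave 56 for ceramide alone. At 6 h EGR1 (3.27, SE 0.25), GDF15 (3.18), ADAM20P1 (2.93) and ANKUB1 (2.53) rose most, and TXNIP (-1.79), MYC (-1.70), TNFAIP6 (-1.64) and CMAHP (-1.59) fell most, among 586 higher and 969 lower genes. At 24 h GDF15 (4.20, SE 0.38), EGR1 (2.67), VGF (2.47) and NQO1 (2.28) rose most, and RN5S63 (-2.77), RAB27B (-2.72), BCRP3 (-2.10) and TNFAIP6 (-1.72) fell most, among 457 higher and 451 lower genes. Of 28 p53 targets 11 rose at 24 h, with CDKN1A at 1.11, and 17 rose adjusted over the list alone (camera adjusted p = 3.33e-20, and adjusted p = 0.000508 with an estimated correlation). Of the 140, 83 and 480 genes that ceramide changed at 3, 6 and 24 h, 73, 65 and 261 were also called in the same direction with PJ34 present, and 1 gene at 24 h in the opposite direction. These comparisons share the control arrays. Their correlation across genes was 0.54, 0.61 and 0.61 against 0.50 in simulated unchanged groups, and the covariance was 0.0253, 0.0312 and 0.0346 against 0.0133, 0.0133 and 0.0134. With the control arrays divided in the same way, 7 to 27, 3 to 32 and 29 to 59 genes were called in both, and the mean covariance was 0.0133, 0.0185 and 0.0244, against -0.0001, 0.0002 and 0.0008 in the divided simulation. Without control 3 h replicate 1 or 2 the 3 h count was 390 or 346, and without inhibitor 6 h replicate 1 the 6 h count was 992. The 24 h count was 570, 542 and 536 without control replicate 1, 2 and 3, and 441 and 473 without inhibitor replicate 2 and 3.

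Untreated cells themselves changed between 3 and 24 h. CCL2, a chemokine, fell by 3.28 on the log2 scale (SE 0.18, adjusted p = 2.64e-11, 3 arrays per group), and TNFRSF12A (-3.09), EGR1 (-3.09) and CCN1 (-2.70) fell with it. BCRP3 (2.08), RN5S104 (1.99), ANKRD29 (1.97) and FLRT1 (1.82) rose most. Of 36 immediate early genes 16 fell and 1 rose, with NR4A1 (-1.48) and KLF6 (-1.42) among them, and 17 fell and 1 rose adjusted over the list alone (camera adjusted p = 1.18e-16, and adjusted p = 0.00975 with an estimated correlation). Of 30 mesenchymal markers 8 fell, including SNAI2 (-1.39), LUM (-0.99) and SOX9 (-0.93), and 8 fell adjusted over the list alone (camera adjusted p = 2.13e-06, and adjusted p = 0.00975 with an estimated correlation). Of 30 noradrenergic markers 7 rose and 3 fell, with HAND1 (1.13) and CHGA (1.37) higher and SCG2 (-1.37) and NEFM (adjusted p = 0.0001) lower, and 13 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.0158, and adjusted p = 0.431 with an estimated correlation). In all, 414 genes were higher and 381 lower at 24 h. Leaving out control 24 h replicate 1 or control 3 h replicate 3 gave 474 or 482. The 474 were 196 higher and 278 lower. With the array interquartile range as a covariate the split was 599 higher and 776 lower, and with array weights it was 1112 higher and 835 lower.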

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

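The tests of array quality, of dividing cells and of gene length as the whole cause were chosen after the results they bear on had been seen, and the test of gene length was chosen before. Genes whose response differed between 3, 6 and 24 h, by limma's F test of the difference itself, numbered 45 for C2-ceramide against control and 32 for PJ34 with ceramide against ceramide alone. In 100 draws of the array splits, the real one included, 2 gave as many as 45, with the highest other at 116, and 3 gave as many as 32, with the highest other at 107. These draws also break the effect of treatment itself. A draw that swaps the labels at a single time turns that effect into a difference between times, and mixed groups widen the spread. The counts of splits thus cannot decide whether the 45 and 32 genes arose by chance.

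Among the genes named for ceramide, the adjusted p of the difference between times was 0.00137 for CCN1, CSRP1, LAMB4 and MINAR2, 0.00017 for KLF6, 0.00279 for CNN2, 0.00733 for SUSD2, 0.0109 for ARID5B and 0.0116 for KLF2 and VGF. It was 0.0117 for TNFRSF12A, 0.0184 for EIF2AK3, 0.0253 for TAS2R3, 0.0267 for CNTNAP4 and JUN, 0.0268 for EPPK1 and 0.0383 for GCM1. Genes lowered early included ARID5B (-1.13, -0.23 and -0.02 at 3, 6 and 24 h) and EIF2AK3 (-1.07, -0.20 and 0.32), while JUN (-0.22, 0.83 and 1.82) and VGF (0.63, 1.42 and 2.47) were highest at 24 h. Among those named for PJ34 with ceramide it was 8.95e-07 for PURPL, 3.75e-05 for C2orf66, 0.00396 for ANKUB1, 0.00398 for DOK4, 0.0042 for ADAM20, 0.0201 for LAMB4, 0.0287 for PDE7B and 0.0365 for LHX4-AS1.

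Probe sets with several gene symbols or none, which the report's comparisons do not use, also carried a signal. Over 29746 such probe sets, 146, 36 and 46 were called with C2-ceramide against control at 3, 6 and 24 h, and 273, 161 and 14 with PJ34 added to ceramide. At 3 h 133 of the 146 were higher with ceramide.

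The higher p53 targets with PJ34 at 24 h (median log2 difference 0.44) were weighed against array quality and against a larger share of dividing cells. Without the 2 least correlated arrays, of which C2 replicate 3 belongs to this comparison, the median was 0.34, 6 members were called and camera's adjusted p was 1.95e-16, which argues against array quality as the whole cause. The p53 targets' median exceeded that of the mitosis list by 0.29, with a bootstrap SE of 0.08, but more dividing cells would not by themselves raise p53 targets, so this excess does not bear on the share of dividing cells. The mitosis and G2/M list was itself higher in 45 of 58 members (median 0.15, camera adjusted p = 0.00276, and adjusted p = 0.171 without those 2 arrays), and the DNA replication and G1/S list in 33 of 44 (median 0.15, camera adjusted p = 0.00647, and adjusted p = 0.0204 without those 2 arrays). With an estimated correlation the adjusted p was 0.952 for both. A difference in dividing cells thus stays open. Spliceosomal and other small nuclear RNAs were lower in 17 of 17 in the same comparison (median -0.42), but their median was -0.01 without those 2 arrays. A response to PJ34 in the presence of ceramide, which the design names, is a hypothesis that remains open, and so is an effect of PJ34 on other proteins, since no group received PJ34 alone.

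The excess of lower over higher genes with PJ34 at 6 h (69.5% lower) was weighed against array quality and gene length. With the array interquartile range as a covariate 51.4% were lower, but all 455 calls were kept, and the share fell because 478 genes were then called higher and 506 lower. Among the 455 genes with the smallest p in that fit 55.6% were lower (exact binomial 95% interval 50.9 to 60.2, though genes are not independent), between the limits of 55% and 60% that would have decided for or against array quality. There were 95 higher and 133 lower genes without inhibitor replicate 1, 183 and 281 after quantile normalization and 542 and 866 with array weights, which count more variable arrays less. Lower genes outnumbered higher ones under each alternative run for this comparison, but how far array quality adds to the imbalance is undecided. The median genomic span of protein-coding genes called lower was 2.21 times that of all 17017 tested protein-coding genes (2.00 times that of sets matched on mean expression), and Spearman's rho of span and log2 difference across genes, which are not independent replicates, was -0.13, against 0.01 for ceramide alone at 6 h, with spans known for 94.5% of genes, so longer genes may fall more with PJ34 at 6 h. Among protein-coding genes shorter than the median span 85 were called lower and 59 higher (exact binomial p = 0.0369), which argues against length as the whole cause, though the genes are not independent. Genes called lower with PJ34 had 1.46 times the median span at 3 h and 0.87 times at 24 h, so the excess of long genes was not seen at 24 h. Genes that ceramide alone lowered were also long (1.59, 1.96 and 1.59 times the median at 3, 6 and 24 h), though across all genes ceramide alone showed no such trend at 6 h.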

How the results depend on the processing

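The array interquartile range as a covariate and the fit without the 2 least correlated arrays were chosen after the data were seen, as was the division of shared arrays, and the other settings named here before. No named gene result called in the main fit changed direction, and changes of sign among those not called there were not counted. Over 593 named gene results and 8812 alternatives, 8032 stayed on the same side of the threshold, 549 no longer passed and 231 newly passed. The arrays varied unequally. The leading axis of the differences within groups held 33.8% of the residual variance. It followed the array interquartile range (r = -0.94, permutation p = 1e-05, Spearman's rho = -0.93, permutation p = 1e-05, 27 arrays, r = -0.89 without the 2 most extreme). Both p-values are the smallest these permutations can give. Axis and range come from the same expression values, and no separate measure of array quality was used. Most counts were higher when the more variable arrays weighed less. In the order 3, 6 and 24 h, array weights gave 279, 212 and 1611 genes for C2-ceramide against control, 1408 and 376 at 6 and 24 h for PJ34 with ceramide against ceramide alone, and 2612 and 2537 at 6 and 24 h for PJ34 with ceramide against control. They gave 1947 for control cells over time, 2193 and 2029 for the means of the 3 times, and 257 and 126 for the differences between times. With the array interquartile range as a covariate, the counts were 279, 259 and 1355, then 399, 984 and 314, then 1223, 2677 and 1736, with 1375 for control cells over time, 2324 and 2243 for the means, and 183 and 103 for the differences between times. Without the 2 least correlated arrays they were 216 and 172 at 3 and 6 h for ceramide against control, 871 at 6 h for PJ34 with ceramide against ceramide alone, 2407 and 1554 at 6 and 24 h for PJ34 with ceramide against control, 1380 for control cells over time, 1455 for the mean of ceramide against control, 102 and 17 for the differences between times, 13 lists for PJ34 with ceramide against control at 3 h, and 43 genes called in both steps at 6 h. A fit of only the groups compared gave 56 and 20 genes at 3 and 24 h for ceramide against control, 0 (limma, 1241 at an unadjusted p under 0.05) and 1 at 3 and 24 h for PJ34 with ceramide against ceramide alone, and 38 at 3 h for PJ34 with ceramide against control, fewer than the 56 for ceramide alone. It estimates the spread from 6 arrays in place of 27. Quantile normalization gave 308 genes at 3 h for PJ34 with ceramide against ceramide alone and 36 called in both steps at 24 h, and eBayes with trend and robust gave 49 for its difference between times, where leaving out the 30% dimmest genes gave 50. With an estimated correlation between genes, camera called 0, 1 and 2 lists for ceramide against control, 0, 0 and 1 for PJ34 with ceramide against ceramide alone, and 0, 0 and 1 for PJ34 with ceramide against control. Where it called 0, the lists at an unadjusted p under 0.05 were 2 for ceramide at 3 h, 1 and 4 for PJ34 against ceramide alone at 3 and 6 h, and 4 and 4 for PJ34 with ceramide against control at 3 and 6 h, and fry called 0, 0, 2, 3 and 11 in the same order. Apart from constructions with fewer arrays, the cause of these changes was not tested.

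No pairing of the arrays by replicate number was detected. Of 27 pairs with the same number 7 had deviations correlated above 0.1 (range -0.34 to 0.24), and 5 of 27 arrays correlated best with their own number. These values cannot show that the arrays were unpaired, since the leading axis of the deviations followed the array interquartile range. The replicate block gave 65 genes at 24 h for PJ34 with ceramide against ceramide alone, 16 for its difference between times and 10 called in both steps at 24 h, and moved no other total by more than 1.5 times. Within totals, the genes higher with PJ34 than with ceramide alone in the mean of the 3 times went from 313 to 201, and the genes called in both steps with opposite signs from 7 to 4 at 6 h and from 16 to 6 at 24 h. It was not run for control cells over time, whose blocks lie within a time. Leaving out each array in turn gave 79 to 113, 46 to 69 and 117 to 712 genes for ceramide against control, 81 to 299, 160 to 231 and 35 to 132 for PJ34 with ceramide against ceramide alone, 346 to 942, 992 to 1240 and 441 to 648 for PJ34 with ceramide against control, and 474 to 654 for control cells over time. The means of the 3 times ranged over 654 to 1080 and 770 to 1297, and the differences between times over 25 to 56 and 10 to 61. The extremes came without C2 24 h replicate 2 (117) and replicate 1 (712) for ceramide at 24 h.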

Other observations

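The tests of array background and of neighbouring genes were chosen after the results they bear on had been seen, and the test of noncoding genes and all counts of splits were chosen before. With C2-ceramide at 24 h, 3 of 24 double-strand break repair genes fell, BRIP1 (-0.78), EXO1 (-0.62) and FANCI (-0.47), and 9 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.000104, and adjusted p = 0.506 with an estimated correlation). Of 49 autophagy and lysosome genes SQSTM1 (0.87), WIPI1 (0.55) and NEU1 (0.45) rose, and 4 rose adjusted over the list alone (camera adjusted p = 0.000515, and adjusted p = 0.49 with an estimated correlation). Among 35 ribosome biogenesis genes 34 were lower (median -0.27), MYC fell (-0.70), and 14 fell adjusted over the list alone (camera adjusted p = 4.19e-10, and adjusted p = 0.134 with an estimated correlation). Spliceosomal and other small nuclear RNAs were higher in 15 of 17 (median 0.44, camera adjusted p = 0.000104, and adjusted p = 0.534 with an estimated correlation), but without the 2 least correlated arrays, of which C2 24 h replicate 3 belongs to this comparison, their median was 0.07 (camera adjusted p = 0.482). The mesenchymal marker SNAI2 was above control (0.73), as were the chemokine gene CCL2 (1.06), the leukocyte-list gene CD68 (0.88) and the ADP-ribose hydrolase gene MACROD2 (0.62). SNAI2 and CCL2 fell in control cells between 3 and 24 h, as given above. Their differences thus need not be a rise within the ceramide group.

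With PJ34 added to ceramide, DHCR7, the last enzyme of a cholesterol synthesis branch, fell at 3 h (-0.55) and 6 h (-0.86), and RRM2, a subunit of ribonucleotide reductase, fell at 6 h (-0.68). The histone genes H2BC18 and H2BC5 rose at 6 h (1.07 and 0.71) and 24 h (1.21 and 0.80). Of 19 replication-dependent histone genes only 2 were called higher at 6 h, and 0 lower. Most members lay the other way, with 14 lower and 5 higher (median -0.24, camera adjusted p = 0.527). CD14 rose at 3 h (0.58) and 6 h (0.71), XBP1 fell at 6 h (-0.60), and the immediate early gene IER5 rose at 24 h (0.67).

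The genes called higher with C2-ceramide at 3 h had a median log2 level of 5.23, against 4.66 for all genes tested. As a set they were thus not weaker than the typical tested gene. No dim genes were left out of that reference, so whether the set is weakly expressed is not settled. All 93 kept their call with the array interquartile range as a covariate (100%), but so did all 5384 calls of the 10 comparisons, so this does not decide on array background, which stays open. Noncoding genes made up 28% of them, 26 genes, against 18.2% of all genes tested (Fisher's exact p = 0.0213) and 15.1% of sets matched on mean expression, and with a wider definition of noncoding, set after the share was seen, 28.9% against 19.5% (p = 0.0318). Adjacent genes on a chromosome were both called in 5 pairs, against a mean of 0.47 and a highest of 4 in 1000 matched random sets (permutation p = 0.001, the smallest they can give). The pairs were LOC374443 with CLEC2D, SLC6A16 with MIR4324, SDHAP2 with MIR570HG, TAS2R3 with TAS2R4 and TAS2R4 with TAS2R5. The last 2 share TAS2R4, so the 5 pairs are not separate loci. A candidate explanation is transcription that runs across neighbouring genes, and probe sets that read the same overlapping transcript stay open as well, since strand and probe positions were not used here.

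The array splits were counted for each result, the real split included. Averaged over the times, 1 of 100 draws gave as many genes as the real split for ceramide against control (925, highest other 233) and 1 of 100 for PJ34 with ceramide against ceramide alone (1072, highest other 610), so a chance split is excluded at 0.05 for both. Single times have 10 splits, too few for a share under 0.05. For genes, 1 of the 10 splits was as high as the real one in every comparison, the real split itself. The real values and the highest others were 140 and 0, 83 and 0 and 480 and 0 for ceramide against control at 3, 6 and 24 h. They were 202 and 3, 455 and 1 and 124 and 2 for PJ34 with ceramide against ceramide alone, 642 and 1, 1555 and 0 and 908 and 0 for PJ34 with ceramide against control, and 795 and 0 for control cells at 24 against 3 h. For gene lists by camera with the preset correlation, 2, 1 and 3 of the 10 splits were as high for ceramide against control (real 9, 11 and 11, highest other 12, 8 and 13). The numbers were 5, 8 and 6 for PJ34 with ceramide against ceramide alone (real 6, 4 and 8, highest other 12, 9 and 13) and 4, 2 and 3 for PJ34 with ceramide against control (real 8, 9 and 10, highest other 11, 10 and 12). Wrong splits thus call as many lists as the real one in most comparisons, and a list called only by camera with the preset correlation carries little weight. With fry, 0, 1 and 9 lists were called for ceramide against control, 0, 2 and 1 for PJ34 with ceramide against ceramide alone, and 3, 11 and 12 for PJ34 with ceramide against control. For ceramide at 24 h the fry FDR was 0.00395 for the mitosis, DNA replication and ATF4 lists. Splits were not counted for fry or for single lists.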
